A study of Macaca mulatta with 10 samples.

How the data were processed

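Whole testes of 10 juvenile male rhesus macaques (Macaca mulatta) were profiled by sequencing of strand-specific total RNA libraries. Per the labels, each animal received a pulsatile intravenous infusion of vehicle or of the gonadotropins FSH and LH, the pituitary hormones that act on Sertoli and Leydig cells. The groups were vehicle with 3 animals, gonadotropin for 48 h with 3 animals and gonadotropin for 96 h with 4 animals. The labels used here do not say for how long vehicle was given. Libraries are named by the animal numbers of the labels, TP07 to TP18. Vehicle animals TP07, TP09 and TP11 were 24, 14 and 15 months old. The 48 h animals TP08, TP10 and TP12 were 22, 14 and 15 months old, and all 96 h animals (TP15 to TP18) were 14 months old. Each library comes from a separate animal, so p-values measure the spread between animals. The labels give no sequencing batch. The 96 h animals are TP15 to TP18 and all others TP07 to TP12, so a batch by animal number would coincide with the 96 h group and cannot be told apart from it.

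Per the submitters' processing notes, the tools used upstream were cutadapt 1.9.1, TopHat2 2.1.1, Bowtie2 2.2.8, Cufflinks 2.2.1, HTSeq 0.6.1p1 and edgeR, with the rheMac8 genome. The authors deposited whole-number counts per locus for every animal. The deposited CPM columns equal each count divided by the library's total over the loci kept in the table, without a further scaling factor, which was checked on the file. The deposited table also holds the authors' log2 fold changes and the authors' p-values. These were used only where the authors' deposited table is named. A second deposited table lists CPM for loci of the vehicle testes, and only gene symbols were taken from it.

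The table holds 26813 loci, assembled from the reads as well as from annotation. Every locus reached a CPM of 1 in at least 3 libraries, so genes below that level were not analysed here. Library totals ran from 21824233 to 30375928 counts, and kept loci held 98.53% to 98.96% of each library's unfiltered total. A floor of 3 counts corresponds to 0.14 CPM in the shallowest library. Floors and count intervals cover counting error only. Of the loci, 30.3% had no annotated name and 12.6% had only an identifier without a symbol. A further 447 joined several gene symbols, whose reads could not be divided. Symbols came from the table for 14383 loci, from the reference gene table of assembly T2T-MMU8v2.0 by NCBI gene ID for 330, and from the authors' second table for 151. This gave 14151 distinct symbols. Where several loci carried 1 symbol, the locus with the highest mean count stood for it. Coordinates are exon limits on rheMac8 from the deposited transcript models. All pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 16.3 to 55, so each library counts as 1 replicate.

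Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust glmQLFit and glmQLFTest). All 10 libraries entered 1 fit of group means, with Benjamini-Hochberg adjustment at 0.05. The expression filter of edgeR removed 0 loci, and the biological coefficient of variation was 0.259. Log2 fold changes are moderated by edgeR's prior count, and their SE was taken from the quasi-likelihood F statistic. CPM values of genes are TMM-scaled, unlike the deposited ones, and are given as mean ± SD over animals. Ratios of pooled counts and the limits for loci near 0 use library totals without that scaling. Lists of genes were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over 28 lists and 3 comparisons. The list tests were repeated with an estimated correlation and with fry. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.

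The comparisons, tests, lists and the rule for named genes were fixed before the data were examined. The rule named 16 genes in every comparison, of which 14 were measured (GDNF and STRA8 were not analysed here). It also named the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 0 and no overlap between the libraries of the groups. Of each list it named up to 4 called members with the smallest p, or up to 2 members as values where none was called. Some genes that the rule named are not reported here. HSD3B2, CYP11B1, HBA1 and other members of near-identical gene families may share reads with their copies, and their values are uncertain for that reason. Alternatives covered scaling (RLE and upper quartile), count filters, exactTest, DESeq2 1.42.0, voom, fits of the compared groups alone and age as a covariate. They also covered omission of the animals over 20 months, stricter thresholds, summed loci, thinned counts and omission of each animal. A correction for exonic length, a fit of loci with 1 symbol and a fit with age class (14, 15 or over 20 months) as a block were added after seeing the data. All 96 h animals, but only TP09 of the vehicle animals and TP10 of the 48 h animals, were 14 months old. The block therefore lowers power in both 96 h comparisons, and a lost call does not show that age accounts for it.

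The test was tried on counts simulated from the real means, dispersions and library sizes of 26813 loci, pooled over 8 draws with 200 changed genes each. Of genes changed 2-fold, 32.1% were recovered for 48 h against vehicle, 36.6% for 96 h against vehicle and 33.8% for 96 h against 48 h. Recovery of 4-fold changes was 77.7%, 78.2% and 77.1% in the same order. Recovery of 1.5-fold changes was 6%, 10.1% and 7.1%. The adjusted threshold loosens as more loci change, so these shares hold for 200 changed genes and not for the real comparisons. False calls made up 6.1%, 6.4% and 5.3% of the simulated calls, slightly above the nominal rate.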

Results

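Testis RNA was sequenced from 10 juvenile rhesus macaques after infusion of vehicle (n = 3) or of FSH and LH for 48 h (n = 3) or 96 h (n = 4). The series asks which genes change as undifferentiated spermatogonia, the stem and progenitor germ cells of the juvenile testis, commit to differentiation. Total counts over kept loci ran from 23607039 to 29230966 in vehicle libraries, from 27824411 to 30375928 at 48 h and from 21824233 to 27684954 at 96 h. Loci without an annotated name took 6.49% ± 0.655 of the counts in vehicle (SD, n = 3), 5.17% ± 0.635 at 48 h (n = 3) and 5.85% ± 0.512 at 96 h (n = 4). Mitochondrial transcripts took 2.82% ± 0.2, 2.18% ± 0.708 and 2.46% ± 0.484 in the same order.

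The first comparison asks what 48 h of gonadotropin changed relative to vehicle. Genes of Leydig cells, the testosterone-producing cells that respond to LH, had the highest median rise among the 28 lists. STAR, which carries cholesterol into mitochondria (chromosome 8, 38419816 to 38428667 on rheMac8), was 419 ± 122 CPM at 48 h and 21.6 ± 10.6 CPM in vehicle (SD, n = 3 each). Its log2 fold change was 4.28 ± 0.51 (SE, edgeR adjusted p = 0.00127). CYP11A1 and CYP17A1, enzymes of steroid synthesis, rose by log2 fold changes of 3.81 ± 0.31 and 3.49 ± 0.21. INSL3, a peptide hormone of Leydig cells, rose by 2.79 ± 0.36. GFRA1, the GDNF co-receptor of undifferentiated spermatogonia (chromosome 9, 111969717 to 112194495), fell from 54.6 ± 8.89 to 17.1 ± 3.97 CPM, a log2 fold change of -1.67 ± 0.23 (edgeR adjusted p = 0.00181).

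Over all 14151 loci standing for a symbol, 2051 rose and 467 fell at 48 h, the shares to set the counts of a list against. Of 17 measured genes of Leydig cell steroidogenesis, 13 rose and 0 fell (14 rose adjusted over the list alone). Their median log2 fold change was 1.34 (camera adjusted p = 1.76e-13, and adjusted p = 0.02 with an estimated correlation). This was the only list call that held with an estimated correlation in any comparison. HSD3B2 rose from 33.9 ± 3.82 to 124 ± 28.4 CPM and TSPO from 64 ± 3.48 to 125 ± 7.03 CPM. LHCGR, the LH receptor, was 43.8 ± 7.63 CPM at 48 h and 24.8 ± 7.09 CPM in vehicle and did not pass the test (edgeR adjusted p = 0.212). Of 21 genes of cholesterol synthesis and uptake 20 rose (21 adjusted over the list alone). Among them FDPS and STARD4 had log2 fold changes of 1.38 ± 0.18 and 1.25 ± 0.20 (camera adjusted p = 3.02e-15, and adjusted p = 0.323 with an estimated correlation). Without both animals over 20 months, 8 Leydig and 4 cholesterol genes rose. The Leydig median was then 1.17, and the cholesterol median was 0.78 (0.84 with all animals). Fewer calls thus came with little change in the medians.

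Genes that copy DNA rose as well. Of 22 DNA replication licensing genes 17 rose (19 adjusted over the list alone), and 7 rose without both animals over 20 months. Their median log2 fold change was 0.73 without those animals and 0.81 with them. The helicase subunits MCM3 and MCM5 had log2 fold changes of 1.45 ± 0.13 and 1.43 ± 0.17 (camera adjusted p = 2.73e-14, and adjusted p = 0.323 with an estimated correlation). Of 21 mitotic cell cycle genes 6 rose (9 adjusted over the list alone). The nucleotide synthesis genes TYMS, TK1 and RRM2 had log2 fold changes of 1.77 ± 0.18, 2.12 ± 0.30 and 1.72 ± 0.25 (camera adjusted p = 9.61e-06, and adjusted p = 0.589 with an estimated correlation). MKI67, a marker of dividing cells, was 46 ± 16.1 CPM against 23.2 ± 9.4 CPM and did not pass (edgeR adjusted p = 0.0699). MKI67 passed with exactTest, DESeq2, age as a covariate, age class as a block and the length correction, and without TP11. Mitotic genes that rose were 12 with age class as a block and 3 under upper-quartile scaling or without both animals over 20 months. Their median was 0.47 in each of the latter fits, against 0.6 as reported. Without TP07, TP09 or TP12, 3 mitotic genes rose in each case, and 10 rose without TP11.

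Glycolysis and lactate export rose in 12 of 20 genes (13 rose and 1 fell adjusted over the list alone). TPI1, PKM and the lactate transporter SLC16A1 had log2 fold changes of 1.02 ± 0.10, 0.84 ± 0.09 and 0.97 ± 0.10 (camera adjusted p = 1.68e-08, and adjusted p = 0.215 with an estimated correlation). In the heat shock and unfolded protein list 7 of 18 genes rose and 1 fell (8 and 1 adjusted over the list alone). The chaperones HSPA5 and HSPD1 had log2 fold changes of 0.96 ± 0.09 and 0.92 ± 0.10 (camera adjusted p = 7.8e-05, and adjusted p = 0.363 with an estimated correlation). Without both animals over 20 months 4 genes of that list rose, with a median of 0.32 (0.33 with all animals).

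Among peritubular myoid and smooth muscle genes 4 of 14 rose (6 rose and 1 fell adjusted over the list alone). The contractile gene ACTA2 was 128 ± 28.2 CPM against 18.9 ± 6.26 CPM (camera adjusted p = 0.00821, and adjusted p = 0.589 with an estimated correlation). Of 24 collagen and matrix genes FBN1, SPARC and VCAN rose (3 adjusted over the list alone; camera adjusted p = 0.00122, and adjusted p = 0.699 with an estimated correlation). That share of collagen rises is near that of all symbols at 48 h (2051 of 14151). SPARC and VCAN did not pass with age class as a block. Omission of any 1 of the 6 animals left 2 peritubular genes higher, and omission of TP07, TP11, TP08 or TP10 left 1 collagen gene higher. Peritubular rises were 2 under upper-quartile scaling or without both animals over 20 months. Collagen rises were 11 with exactTest, 5 with DESeq2 and 0 without both animals over 20 months. The collagen median without those animals was 0.51, against 0.67 with all animals. Of 17 macrophage genes 0 passed edgeR's test, also adjusted over the list alone, and their median log2 fold change was 0.55 (camera adjusted p = 0.0381, and adjusted p = 0.755 with an estimated correlation). The macrophage list did not pass with age as a covariate or the length correction, nor without TP07, TP10 or both animals over 20 months.

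Sertoli cells nurse germ cells and carry the FSH receptor. Of 18 Sertoli identity genes 5 rose (5 rose and 1 fell adjusted over the list alone). INHA, the inhibin alpha subunit, rose from 404 ± 44.2 to 806 ± 159 CPM and the tight junction gene CLDN11 from 58.8 ± 7.66 to 148 ± 40.4 CPM (camera adjusted p = 0.0432, and adjusted p = 0.589 with an estimated correlation). Without TP07, TP09, TP08 or TP12, 3 of them rose in each case, as under upper-quartile scaling, and 1 rose without both animals over 20 months. The list did not pass camera with the length correction, nor without TP11, TP08 or TP12. Of 24 FSH and cAMP responsive genes 4 rose (6 adjusted over the list alone), a share near that of all symbols at 48 h (2051 of 14151). In that list 2 rose without TP07, TP09 or both animals over 20 months and 7 rose with exactTest or DESeq2. That list did not pass camera without TP07, TP12 or both animals over 20 months. CITED1 and DIO2 had log2 fold changes of 1.14 ± 0.24 and 1.43 ± 0.37 (camera adjusted p = 0.0283, and adjusted p = 0.441 with an estimated correlation). DIO2 did not pass with age class as a block. FSHR, AMH, INHBB and KITLG did not pass, with log2 fold changes of -0.17 ± 0.20, -0.26 ± 0.18, 0.30 ± 0.20 and -0.15 ± 0.17.

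Of 20 undifferentiated spermatogonial genes GFRA1 and FOXO1 fell (2 adjusted over the list alone), the latter with a log2 fold change of -0.64 ± 0.10 (camera adjusted p = 0.00821, and adjusted p = 0.482 with an estimated correlation). Of 18 pan germ cell genes 1 fell (1 adjusted over the list alone). This was DAZL, an RNA-binding protein of germ cells, at 49.1 ± 8.25 CPM against 89.2 ± 17.9 CPM (camera adjusted p = 0.00442, and adjusted p = 0.699 with an estimated correlation). The pan germ cell list did not pass without TP10. Among 21 differentiating spermatogonial genes UHRF1 and CCND2, which also serve the cell cycle, rose and BEND2 fell (camera adjusted p = 0.943). ZBTB16, a transcription factor of undifferentiated spermatogonia, was 19.2 ± 0.155 CPM against 52.9 ± 34 CPM (edgeR adjusted p = 0.072). KIT, SOHLH1 and DDX4 did not pass either, with log2 fold changes of -0.60 ± 0.23, -0.41 ± 0.24 and -0.47 ± 0.19.

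IGFBP3, a binding protein of insulin-like growth factors (chromosome 3, 63011977 to 63020823), fell from 536 ± 33.2 to 59.2 ± 25.3 CPM. IGF1 rose from 167 ± 83.9 to 606 ± 229 CPM, and PAPPA, a protease of these binding proteins, rose from 25 ± 2.73 to 71.3 ± 14.1 CPM. ANKRD30A (chromosome 9, 36957798 to 37106862) had 4 counts over the 48 h libraries and 1120 over the vehicle libraries. The ratio was 303 in favour of vehicle, with a 95% exact counting interval of 118 to 1110. CYP11B1 had 281 counts at 48 h and 2 in vehicle, a ratio of 130 with an interval of 35.6 to 1080. TP08, TP10 and TP12 were at 7.01, 2.16 and 0.421 CPM, a spread between animals that the interval does not cover. Other large rises were those of DEFB123 and GPR55, with log2 fold changes of 3.85 ± 0.43 and 3.46 ± 0.49. Other large falls were those of GRIP2, KCNS3, TMEM200A and APOD, with -2.12 ± 0.34, -2.08 ± 0.59, -1.99 ± 0.24 and -1.93 ± 0.47. KCNS3 did not pass with age class as a block.

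Over all 26813 loci, edgeR called 3273 at 48 h, 2288 higher and 985 lower, and 7489 had an unadjusted p below 0.05. The libraries of the groups did not overlap at 36.1% of loci, where chance gives 10%. Under upper-quartile scaling the split was 1392 higher and 1732 lower, and the median log2 fold change of all loci moved from -0.071 to -0.197. With the correction for exonic length the split was 2660 higher and 641 lower. The count was 1767 without TP09, 2014 without TP11, 1564 without TP08, 2084 without TP12 and 850 without both animals over 20 months. The authors' deposited table lists 2854 loci at an FDR of 0.05, and 2311 of them were called here in the same direction.

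**Figure D1:**
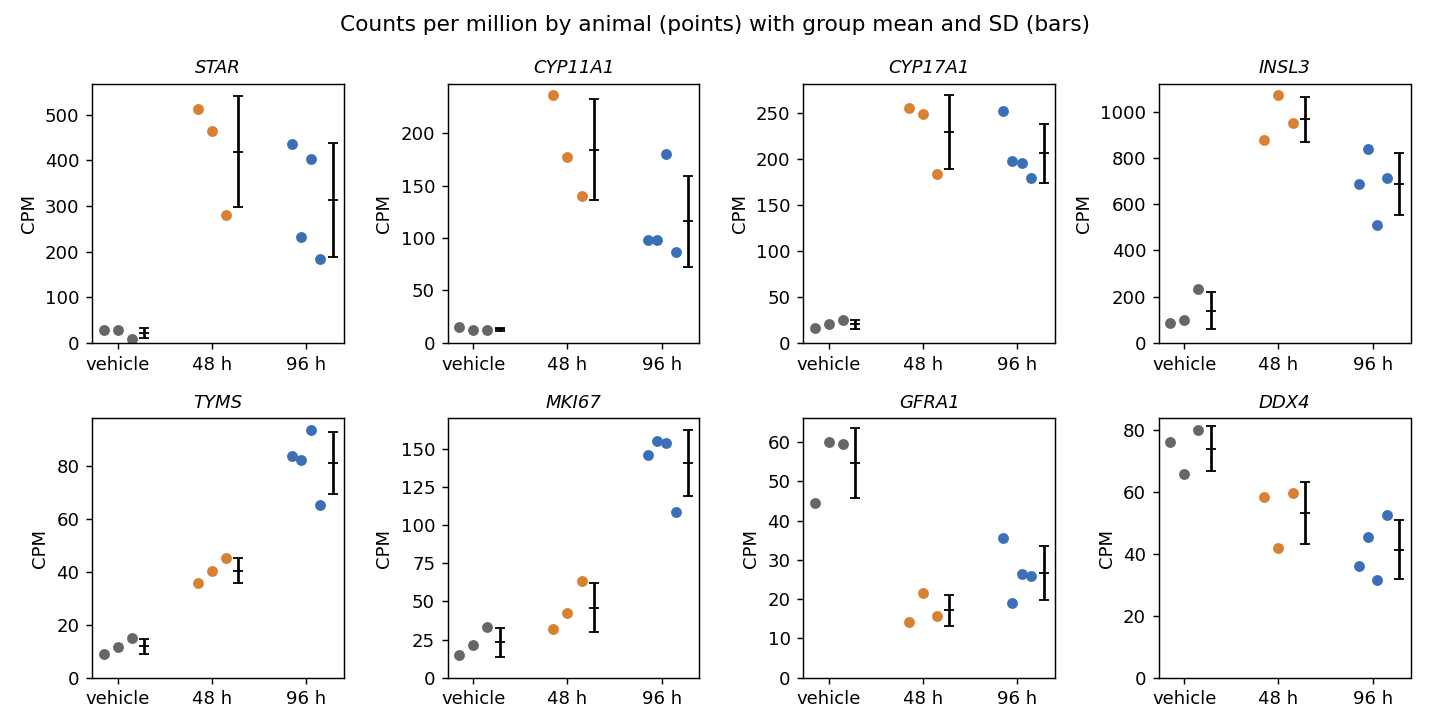
CPM (vertical axis, linear, from 0) of 8 genes in each animal, with 3 vehicle, 3 gonadotropin 48 h and 4 gonadotropin 96 h animals as points and the group mean ± SD as bars. Group means of STAR, CYP11A1, CYP17A1 and INSL3 lie above vehicle at both times, those of TYMS and MKI67 are highest at 96 h, and those of GFRA1 and DDX4 lie below vehicle at both times.

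The second comparison asks what 96 h of gonadotropin changed relative to vehicle. Over all 14151 loci standing for a symbol, 2439 rose and 975 fell at 96 h. Genes of cell division were higher. MKI67 (chromosome 9, 124197684 to 124242638) rose from 23.2 ± 9.4 (SD, n = 3) to 141 ± 21.6 CPM (n = 4), a log2 fold change of 2.61 ± 0.32 (SE, edgeR adjusted p = 0.000992). Of 21 mitotic cell cycle genes 20 rose and 0 fell (20 adjusted over the list alone), with a median log2 fold change of 1.69 (camera adjusted p = 4.01e-22, and adjusted p = 0.323 with an estimated correlation). Of 18 pan germ cell genes 10 fell and 0 rose (12 fell adjusted over the list alone), with a median of -0.74 (camera adjusted p = 4.82e-07, and adjusted p = 0.489 with an estimated correlation).

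Nucleotide synthesis genes TYMS, TK1 and RRM2 rose by log2 fold changes of 2.78 ± 0.18, 3.30 ± 0.30 and 2.90 ± 0.25. Of 22 replication licensing genes 19 rose (20 adjusted over the list alone). CDC6 and MCM3 had log2 fold changes of 1.78 ± 0.17 and 1.41 ± 0.12 (camera adjusted p = 3.02e-15, and adjusted p = 0.323 with an estimated correlation). Of 17 Leydig steroidogenesis genes 11 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 8.99e-08, and adjusted p = 0.0576 with an estimated correlation). STAR was 314 ± 124 CPM, and the log2 fold changes were 3.33 ± 0.20 for CYP17A1, 3.14 ± 0.29 for CYP11A1 and 2.30 ± 0.34 for INSL3. Of 21 cholesterol genes 18 rose (21 adjusted over the list alone), and 11 rose without TP09. Rises with age class as a block were 8 for cholesterol and 6 for Leydig genes, and 7 Leydig genes rose without both animals over 20 months. The Leydig median without those animals was 1.01, against 0.95 with all animals. FDPS was 69.7 ± 13.9 CPM against 32.2 ± 2.25 CPM (camera adjusted p = 4.13e-11, and adjusted p = 0.363 with an estimated correlation).

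Glycolysis rose in 8 of 20 genes (8 adjusted over the list alone), with TPI1 at 182 ± 16.5 CPM against 102 ± 8.53 CPM (camera adjusted p = 0.00217, and adjusted p = 0.441 with an estimated correlation). The heat shock list rose in 6 of 18 genes with 1 fall (6 and 1 adjusted over the list alone; camera adjusted p = 0.00907, and adjusted p = 0.581 with an estimated correlation), and it did not pass camera without TP18. Of 18 Sertoli identity genes 6 rose and 1 fell, and of 24 FSH and cAMP responsive genes 8 rose and 2 fell. Neither list passed (camera adjusted p = 0.45 and 0.117). Sertoli identity genes that rose were 2 without TP07 or TP11 and 3 without TP09, TP16 or TP12. FSH and cAMP genes that rose were 0 without TP07, 2 without TP11, 3 without TP09 or TP15 and 5 without TP17. In the fit with age class as a block, and likewise in that without both animals over 20 months, 3 Sertoli identity and 2 FSH and cAMP genes rose. Under upper-quartile scaling 3 Sertoli identity genes rose and 3 fell, with a median log2 fold change of -0.16, and 4 FSH and cAMP genes rose and 3 fell. FSH and cAMP rises were 4 with age as a covariate and 5 with voom, in a fit of the 2 groups alone or without TP12. Falls in that list were 0 with age as a covariate or without both animals over 20 months. LHCGR, FSHR, AMH, INHBB, KITLG and ZBTB16 did not pass, with log2 fold changes of 0.53 ± 0.37, 0.19 ± 0.19, -0.08 ± 0.17, -0.34 ± 0.18, 0.06 ± 0.16 and -0.73 ± 0.42.

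The germ cell helicase DDX4 fell from 73.9 ± 7.3 to 41.3 ± 9.47 CPM. Of 20 undifferentiated genes 7 fell and 1 rose (10 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.000191, and adjusted p = 0.325 with an estimated correlation). GFRA1 was 26.7 ± 6.85 CPM against 54.6 ± 8.89 CPM, and FGFR3, MORC1 and PIWIL4 had log2 fold changes of -0.97 ± 0.16, -0.84 ± 0.20 and -0.95 ± 0.23. Among 21 differentiating genes 5 fell and 2 rose (camera adjusted p = 0.205). KIT, the receptor of differentiating spermatogonia, and the transcription factor SOHLH1 fell with log2 fold changes of -0.91 ± 0.22 and -1.08 ± 0.22. UHRF1 and CCND2 rose by 2.01 ± 0.15 and 1.00 ± 0.11. Of 20 meiotic prophase genes 4 fell, TEX12, SYCP2 and SYCP1 among them, and MND1 rose (10 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.00821, and adjusted p = 0.589 with an estimated correlation). Of 5 spermatid genes LDHC fell (4 fell adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.39 with an estimated correlation).

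The number of falls moved with the setting and when animals were left out. The number of pan germ cell genes that fell was 5 without TP07, 3 without TP11, 5 without TP17 and 1 without both animals over 20 months. The pan germ cell median without those animals was -0.65, against -0.74 with all animals. For undifferentiated genes the number of falls was 2 without TP07 or TP11 and 4 without TP09, TP15 or TP17. For meiotic genes it was 0 without TP07 and 1 without TP11, and for differentiating genes 1 without TP07 or TP11 and 2 without TP17. Meiotic falls were 8 under upper-quartile scaling or over loci with 1 symbol, 7 with DESeq2 and 0 with age as a covariate or without both animals over 20 months. With age as a covariate 6 pan germ cell, 2 undifferentiated and 1 differentiating genes fell. Undifferentiated falls were 4 in a fit of the 2 groups alone and 2 without both animals over 20 months, where 1 differentiating gene fell. With age class as a block 2 undifferentiated genes fell, and 0 pan germ cell, differentiating or meiotic genes. Among the genes that then did not pass were DDX4, KIT, SOHLH1, MORC1, PIWIL4, TEX12, SYCP2, SYCP1 and LDHC. By camera the meiotic and spermatid lists did not pass with this block, and the undifferentiated and pan germ cell lists passed. The block lowers power at 96 h, as only TP09 of the vehicle animals matched the 96 h animals in age. The lost calls therefore do not show that age accounts for the falls.

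Collagen, macrophage, stromal progenitor and peritubular lists passed camera with higher values, and the endothelial, lymphocyte and mast cell, erythroid and rete testis lists did not pass. The lists that camera called here did not pass fry (fry adjusted p = 0.075, 0.103, 0.0883 and 0.0758 in the order given). Of 24 collagen and matrix genes 14 rose (17 rose and 1 fell adjusted over the list alone). VCAN was 160 ± 67.4 CPM against 39.8 ± 16.8 CPM and FN1 was 225 ± 76.5 CPM against 68.2 ± 35.2 CPM (camera adjusted p = 2.51e-07, and adjusted p = 0.581 with an estimated correlation). Of 17 macrophage genes 5 rose (14 adjusted over the list alone), including CD14 and AIF1 with log2 fold changes of 1.31 ± 0.36 and 1.49 ± 0.38 (camera adjusted p = 1.19e-05, and adjusted p = 0.589 with an estimated correlation). Of 14 immature Leydig or stromal progenitor markers 6 rose (6 adjusted over the list alone), with DLK1, THY1 and IGF1 at 1.52 ± 0.15, 2.25 ± 0.33 and 2.39 ± 0.48 (camera adjusted p = 0.000303, and adjusted p = 0.596 with an estimated correlation). Of 14 peritubular myoid genes 7 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.00515, and adjusted p = 0.581 with an estimated correlation).

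The number of macrophage genes that rose was 0 without TP07, 2 without TP09, 1 without TP11, 2 without TP15, 11 without TP16 and 1 without TP17. For collagen genes it was 6 without TP07 or TP11, 9 without TP15 and 8 without TP17. For peritubular genes it was 2 without TP07, 3 without TP11 and 4 without TP15 or TP17, and for stromal progenitor markers 3 without TP07. Macrophage rises were 14 with DESeq2, 9 with exactTest and 2 with age as a covariate, which left 9 collagen and 4 peritubular genes higher. Without both animals over 20 months it was 0 for macrophage, 3 for collagen and stromal progenitor and 2 for peritubular genes. With age class as a block it was 0 for macrophage and collagen genes, 2 for peritubular genes and 3 for stromal progenitor markers, and all 4 lists passed camera. Medians without both animals over 20 months were 0.8, 1.1, 0.39 and 0.68 for macrophage, collagen, stromal progenitor and peritubular genes. With all animals they were 1.13, 1.28, 0.62 and 0.84. Both fits have less power, so the lost calls do not show that age accounts for the rises.

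Among the genes with the highest rises, MRO and RASD1 had log2 fold changes of 3.73 ± 0.28 and 3.67 ± 0.23. CYP11B1 had 201 counts at 96 h and 2 in vehicle, a ratio of 84.1 with a 95% exact counting interval of 23 to 699. The 96 h animals ran from 0.651 to 3.92 CPM, a spread that the interval does not cover. HRK, SLC34A2, ADH7, L1CAM and COL26A1 fell with -2.46 ± 0.36, -2.36 ± 0.31, -2.26 ± 0.42, -2.20 ± 0.51 and -2.17 ± 0.46. IGFBP3 was 110 ± 58.2 CPM against 536 ± 33.2 CPM. IGFBP3 and L1CAM did not pass with age class as a block.

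Over all loci edgeR called 4684 at 96 h, 2836 higher and 1848 lower, with 9143 at an unadjusted p below 0.05. Group ranges did not overlap at 30.7% of loci, where chance gives 5.7%. Under upper-quartile scaling the split was 1687 higher and 3532 lower, and the median log2 fold change of all loci moved from -0.012 to -0.16. The count was 2210 without TP07, 3086 without TP09, 2319 without TP11, 2798 without TP17 and 1940 without both animals over 20 months. With age as a covariate it was 3071, of which 2210 were higher, and with age class as a block 1762, of which 1350 were higher. The 96 h animals are TP15 to TP18 and the others TP07 to TP12, so a batch by animal number cannot be told apart from the 96 h group in this comparison or in that with 48 h. The authors' deposited table lists 3886 loci at an FDR of 0.05, of which 3428 were called here in the same direction.

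Further lists did not pass camera at either time. At 48 h the rises among immediate early, Sertoli junction and retinoid genes lay near the share of all symbols (2051 of 14151). Of 19 immediate early genes 3 rose at 48 h and 2 at 96 h, with MYC and DUSP1 higher at both times (camera adjusted p = 0.121 and 0.193), and 5 rose at 48 h with exactTest or DESeq2. Of 15 Sertoli junction genes 2 rose and 1 fell at each time (0.275 and 0.808). Of 19 retinoid genes 3 rose at 48 h, and 6 rose and 2 fell at 96 h (0.119 and 0.101). Retinoid rises at 96 h were 2 without TP07, TP11 or TP17, 1 without TP09 or both animals over 20 months, and 3 without TP15, with age class as a block, under upper-quartile scaling or in a fit of the 2 groups alone. Such a fit gave 5 retinoid rises at 48 h, and 1 rose there without both animals over 20 months. Of 19 spermatogonial niche ligands 1 rose at each time, while 2 fell at 48 h and 3 at 96 h (0.14 and 0.977). Niche falls at 96 h were 0 without TP07, TP17 or both animals over 20 months, with age as a covariate or with age class as a block, and 1 without TP11 or TP15 or in a fit of the 2 groups alone. Of 15 Notch pathway genes 1 rose at 48 h, and 2 rose and 2 fell at 96 h (0.477 and 0.939). Notch falls at 96 h were 0 without both animals over 20 months. Of 17 endothelial genes 0 passed at 48 h and 1 fell at 96 h (0.544 and 0.592). Of 9 lymphocyte and mast cell genes 0 passed at 48 h, and 1 rose and 1 fell at 96 h (0.524 and 0.492). Of 6 erythroid genes 0 passed at either time, also adjusted over the list alone (0.943 and 0.354).

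Of 7 rete testis and epididymis genes 1 rose at 48 h, and 1 rose and 2 fell at 96 h (camera adjusted p = 0.131 and 0.808). Those falls at 96 h were 0 with age as a covariate or without both animals over 20 months. With fry the rete testis list passed as higher at 48 h (fry adjusted p = 0.0146). Of 15 angiogenic factors 1 rose and 2 fell at 48 h, and 3 rose and 2 fell at 96 h (0.943 and 0.72). Angiogenic rises at 96 h were 1 under upper-quartile scaling or with age class as a block. Of 17 genes of the insulin-like growth factor system 3 rose and 4 fell at 48 h, and 5 rose and 5 fell at 96 h (0.944 and 0.997). Falls at 48 h were 2 without TP09 or TP08 and 1 without both animals over 20 months. Falls at 96 h were 0 without both animals over 20 months, 1 without TP07, 2 without TP09 or TP17, with age as a covariate or with age class as a block, and 3 without TP11 or TP15 or with the length correction. Rises at 96 h were 3 with age class as a block. At 48 h the stromal progenitor list had 3 rises (1 without TP07, TP10, TP12 or both animals over 20 months) and 1 fall, and the meiotic and spermatid lists had 0 of either (0.103, 0.183 and 0.281). At 96 h the median and the mean log2 fold change differed in sign for Sertoli identity (-0.01 and 0.28) and for the rete testis list (-0.42 and 0.21). Endothelial genes at 96 h had a median of 0.12 while camera ranked them lower than other genes. That median was -0.04 under upper-quartile scaling, -0.11 with age as a covariate, -0.18 with age class as a block, -0.08 without TP07 and -0.16 without TP15. Without both animals over 20 months the medians were 0.03 for Sertoli identity, 0.01 for the rete testis list and -0.08 for endothelial genes.

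The 48 h and 96 h changes were compared with each other through the vehicle libraries they share. Of the called loci 2074 were called at both times in the same direction, 1608 higher and 466 lower, and 1 in opposite directions. Independent lists of these sizes would share 242 higher and 67.9 lower. In 20 simulated pairs of unchanged groups that shared simulated vehicle libraries at most 0 were shared. Each simulated comparison had at most 3 calls, so this count does not measure overlap from the shared libraries. The log2 fold changes correlated at 0.63 across loci, which are not independent replicates, against a simulated mean of 0.538. Their covariance was 0.287 against a simulated mean of 0.076, a difference of 0.211. The simulated groups held no effect of age, so the simulated mean leaves the ages of the animals out. Vehicle libraries were also drawn anew, each gene on its own. The simulated mean therefore does not measure what the real vehicle animals contribute. The 3 vehicle libraries cannot be divided into parts of 2, so part of the excess may come from the shared controls. The shared count was 1176 without TP07, 1119 without TP09, 1166 without TP11, 1272 without TP08, 646 without both animals over 20 months and 1252 with age class as a block.

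**Figure D2:**
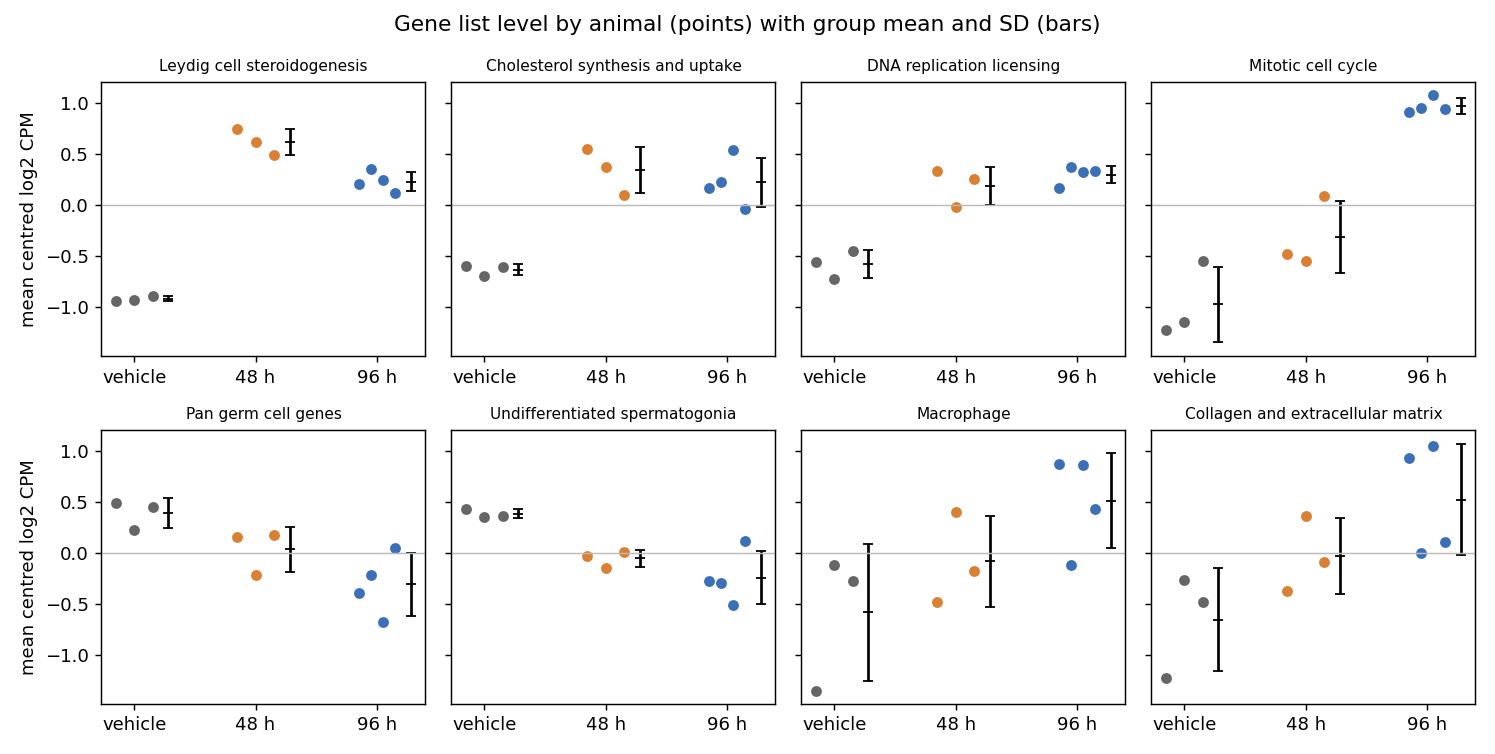
Mean centred log2 CPM (vertical axis) of 8 gene lists in each animal, with 3 vehicle, 3 gonadotropin 48 h and 4 gonadotropin 96 h animals as points and the group mean ± SD as bars. The Leydig list lies between 0.12 and 0.74 in all treated animals and between -0.94 and -0.89 in all vehicle animals, and the mitotic list lies between 0.91 and 1.08 in all 96 h animals.

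The third comparison asks what differed between 96 h and 48 h of gonadotropin. Over all 14151 loci standing for a symbol, 179 rose and 62 fell from 48 h to 96 h. Mitotic genes were higher at 96 h. ASPM, ANLN and NUSAP1, proteins of the spindle and of cell cleavage, rose by log2 fold changes of 2.02 ± 0.29, 1.83 ± 0.23 and 1.76 ± 0.26. MKI67 rose from 46 ± 16.1 (SD, n = 3) to 141 ± 21.6 CPM (n = 4), a log2 fold change of 1.61 ± 0.30 (SE, edgeR adjusted p = 0.0397). FSTL3, an antagonist of activin, fell from 184 ± 21 to 68.6 ± 22 CPM and did not pass with age class as a block.

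Of 21 mitotic genes 16 rose and 0 fell (20 rose adjusted over the list alone). CENPF, KIF20A and KIF11 had log2 fold changes of 1.29 ± 0.16, 1.67 ± 0.21 and 1.47 ± 0.19 (camera adjusted p = 3.28e-27, and adjusted p = 0.282 with an estimated correlation). Without TP08, TP10 or TP17 0 mitotic genes passed edgeR's test, although their median log2 fold change was 1.20, 1.14 and 1.23. Without TP15 9 passed, without TP18 or with age as a covariate 7, and without both animals over 20 months 0. Of 22 replication licensing genes 0 passed (1 rose adjusted over the list alone; camera adjusted p = 0.176). Of 17 Leydig genes TSPO fell from 125 ± 7.03 to 84.4 ± 6.92 CPM (3 fell adjusted over the list alone; camera adjusted p = 2.85e-05, and adjusted p = 0.131 with an estimated correlation). TSPO did not pass with age class as a block. STAR, CYP17A1 and INSL3 did not pass, with log2 fold changes of -0.42 ± 0.41, -0.16 ± 0.17 and -0.49 ± 0.31.

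In 6 further lists camera gave a call while 0 members passed edgeR's test over all genes. Glycolysis had a median log2 fold change of -0.31 (7 fell adjusted over the list alone; camera adjusted p = 3.17e-05, and adjusted p = 0.323 with an estimated correlation). Macrophage genes had a median of 0.55 (2 rose adjusted over the list alone; camera adjusted p = 0.000633, and adjusted p = 0.699 with an estimated correlation). Pan germ cell genes had a median of -0.37 and collagen genes of 0.61 (0 adjusted over the list alone in both; camera adjusted p = 0.000791 and 0.00146, and adjusted p = 0.641 and 0.699 with an estimated correlation). Stromal progenitor markers had a median of 0.54 and niche ligands of 0.32 (1 rose adjusted over the list alone in each; camera adjusted p = 0.00605 and 0.0317, and adjusted p = 0.699 and 0.589 with an estimated correlation). Of these lists only glycolysis passed camera with age class as a block. With age as a covariate the stromal progenitor, niche, macrophage and collagen lists did not pass. The niche list did not pass with the length correction either, nor without TP08, TP15, TP17 or both animals over 20 months, and the stromal progenitor list not without TP15. In lists that camera did not call, PAPPA and the keratin KRT8 fell by 0.67 and 0.80 on the log2 scale, and neither passed with age class as a block.

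GFRA1, ZBTB16, KIT, SOHLH1 and DDX4 did not pass and had log2 fold changes of 0.64 ± 0.22, 0.73 ± 0.44, -0.31 ± 0.22, -0.67 ± 0.22 and -0.36 ± 0.18. LHCGR, FSHR, AMH, INHBB and KITLG had -0.29 ± 0.36, 0.36 ± 0.19, 0.17 ± 0.17, -0.63 ± 0.18 and 0.20 ± 0.16. ANKRD30A had 511 counts at 96 h and 4 at 48 h, a ratio of 116 with a 95% exact counting interval of 44.9 to 426. Other large falls were those of SLC35F2, DMKN and TINAGL1, with log2 fold changes of -1.41 ± 0.13, -1.32 ± 0.20 and -1.14 ± 0.19. DMKN and TINAGL1 did not pass with age class as a block.

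EdgeR called 286 loci, 219 higher and 67 lower at 96 h, with 5614 at an unadjusted p below 0.05. Group ranges did not overlap at 16.5% of loci, where chance gives 5.7%. The count was 2 without TP08, 9 without TP10, 5 without TP17, 186 without TP12, 174 without TP15, 106 without TP18 and 178 with age class as a block. DESeq2 called 1827 and exactTest 704. The authors' deposited table lists 746 loci at an FDR of 0.05, of which 256 were called here in the same direction.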

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

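The tests of other splits and of explanations were chosen after the results were seen, except the count of loci near 0 in other sets of 3 animals, whose bound was set before its value was known. In the 96 h group, 8 of 191 named genes had 1 animal far from the rest, where chance at 1 in 20 gives 9.6. TP17 was at 124 CPM for ANLN (others 109 to 110), 180 CPM for CYP11A1 (87 to 98.6) and 89.9 CPM for FDFT1 (71.1 to 73). TP15 was at 107 CPM for HBA1 (32.6 to 37.2) and 40.2 CPM for PAPPA (45.8 to 46.7). TP16 was at 125 CPM for FOXO1 (96.9 to 99.7). TP18 was at 20.9 CPM for HEYL (30.3 to 31.7) and 0.666 CPM for SLC25A18 (0.289 to 0.339).

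The effects at 96 h and at 48 h differed by edgeR's test between the times for 6 genes named against vehicle. The log2 difference was 6.76 for ANKRD30A, where it rests on 4 counts at 48 h and depends on the prior count. It was 1.67 for KIF20A, 1.61 for MKI67, -0.57 for TSPO, -0.67 for PAPPA and -0.80 for KRT8. TSPO, PAPPA and KRT8 did not pass with age class as a block. With fry the mitotic, Leydig and glycolysis lists differed (fry adjusted p = 0.00292, 0.00505 and 0.0146), as did the rete testis list (0.00769), which camera did not call. The collagen, macrophage, stromal progenitor, niche and pan germ cell lists did not pass fry. By camera with a preset correlation, 8 lists differed, and none of them with an estimated correlation. Their median difference was 1.28 for mitotic genes, 0.61 for collagen, 0.55 for macrophages, 0.54 for stromal progenitor markers, 0.32 for niche ligands, -0.31 for glycolysis, -0.37 for pan germ cell genes and -0.42 for Leydig steroidogenesis. With age class as a block the collagen, macrophage, stromal progenitor, niche and pan germ cell lists did not pass.

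For the counts of changed loci, other splits of the same animals were tried. At 96 h against vehicle 1 of 35 splits, the real one, gave as many as 4684 loci, and the highest other gave 175. For 96 h against 48 h 1 of 35 splits gave as many as 286, and the highest other gave 6. Chance can be excluded in both only if animals of different ages may be exchanged, since these splits disregard age. In each comparison 5 animals were 14 months old, and their 5 splits are too few for a share under 0.05. With age class as a block 4684 became 1762 and 286 became 178. The count of 4684 was 2210 without TP07, 3086 without TP09, 2319 without TP11, 2798 without TP17 and 1940 without the 2 older animals. The count of 286 was 2 without TP08, 9 without TP10, 5 without TP17, 186 without TP12, 174 without TP15, 106 without TP18 and 3 without the older animals. At 48 h against vehicle the 10 splits are too few for a share under 0.05. The real split gave 3273 and the highest other gave 1.

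More loci were higher than lower at 48 h, but not in every class. Loci standing for a symbol gave 2051 higher and 467 lower, and 8122 loci without an annotated name gave 65 and 355. At a change of at least 2-fold 423 were higher and 457 lower. Thinning to the smallest library left 70.6% of calls higher, against 69.9% as reported, which argues against depth as the whole cause. Removing the trend on exonic length left 80.6% higher. That correction also rescaled the libraries and moved the median log2 fold change of all loci from -0.071 to -0.006. Its share follows in part from that shift and does not decide whether length is a cause. Under RLE scaling 74.2% of calls were higher and under upper-quartile scaling 44.6%, where the median log2 fold change of all loci moved from -0.071 to -0.197, so that share follows from the scaling itself and decides nothing. No other value here decides which scaling holds, so the choice of scaling and a real excess of higher loci cannot be told apart. A change in more genes upwards than downwards under gonadotropin stays open for genes with a symbol only.

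ANKRD30A was near 0 in all 48 h animals and above 1 CPM in the others. It ran from 11.1 to 15.8 CPM in vehicle and from 3.76 to 8.5 CPM at 96 h, so all 96 h animals also lay below vehicle. The gene lists used here do not place ANKRD30A in a cell type. If undifferentiated spermatogonia made it, loss of these cells as a whole would lower their other genes by a like amount. The median log2 fold change of the undifferentiated list was -0.42, which under that assumption argues against such a loss. Loss of a part of these cells was not tested. A variant carried by 3 animals that fell in this group by chance is not excluded, but it would not account for the lower values at 96 h. Another 8 loci were near 0 in 1 of the 119 other sets of 3 animals, so 0.067 loci would be expected to pick out the 48 h animals, above the bound of 0.05. A response of the gene to 48 h of gonadotropin stays open as well.

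At 96 h 4 of 5 germ cell lists passed camera as lower with the preset correlation, and 2 of them with age class as a block. None of them passed with an estimated correlation. With fry the undifferentiated, pan germ cell and spermatid lists passed (fry adjusted p = 0.00734, 0.0294 and 0.00814), and the meiotic list did not (0.0794). The median log2 fold change of the pan germ cell list was at most -0.71 under other scalings or with the length correction and -0.65 without the 2 older animals (-0.5 with age class as a block), which argues against both as the whole cause. Dilution by RNA of other cell types is not excluded. It would lower all 5 germ cell lists, whose medians ran from -0.74 to -0.44, but also other cells that did not expand. Medians were -0.01 for Sertoli identity, 0.04 for Sertoli junction and 0.12 for endothelial genes. They were -0.38 for lymphocyte and mast cell and -0.42 for rete testis genes, so these lists do not decide it. The germ cell lists were not found to differ over 84 genes, which are not independent (permutation p = 0.108), and this does not show that they moved alike. A change within germ cells stays open.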

How the results depend on the processing

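The length correction, the fit of loci with 1 symbol and age class (14, 15 or over 20 months) as a block were chosen after seeing the data. The number of loci called at 48 h against vehicle was 5079 with DESeq2, 850 without the 2 animals over 20 months, 2041 with a fold of at least 1.5, 1238 at an adjusted p below 0.01, and 1564 to 2776 without 1 animal. At 96 h against vehicle it was 3071 with age as a covariate, 1762 with age class as a block, 1940 without the 2 animals over 20 months, 1520 at an adjusted p below 0.01, and 2210 to 4554 without 1 animal. For 96 h against 48 h it was 704 with exactTest, 1827 with DESeq2, 95 with age as a covariate, 178 with age class as a block, 3 without the 2 animals over 20 months, 5 at an adjusted p below 0.01, 484 over loci with 1 symbol, and 2 to 344 without 1 animal. A stricter threshold lowers a count by construction. Omission of an animal mostly lowered counts but also raised some (344 for 96 h against 48 h without TP16), and the cause was not tested. The loci shared by both times were 1252 with age class as a block, 646 without the 2 animals over 20 months and 1119 to 1974 without 1 animal. The number of lists called was 1, 0 and 0 with an estimated correlation and 8, 9 and 4 with fry for 48 h, 96 h and 96 h against 48 h, and 5 for the last with age as a covariate, against 13, 14 and 8 as reported. Without 1 animal it was 11 to 15, 13 to 15 and 7 to 12. Of the 13 lists called at 48 h, the mitotic, Sertoli identity, pan germ cell, peritubular, macrophage and collagen lists did not pass with fry.

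Among the values of named genes and of the lists that camera called, under the alternatives, 6793 kept their direction and side of the threshold, 716 no longer passed it, 81 newly passed it and 9 changed sign. Those 9 belong to 3 genes that did not pass the test. The 6793 include values from both count filters, which could not differ, and from stricter thresholds, which cannot change a sign. Many of the genes were named for their strong change in the same data, so this tally overstates stability. Medians of lists that camera did not call are not in these counts, and several changed sign, such as niche ligands at 96 h from 0.06 to -0.1 under upper-quartile scaling. FSHR at 48 h was 0.10 with the length correction (-0.17 as reported). AMH at 96 h (-0.08) was 0.15 without TP09 and 0.01 without TP17, in a range of -0.21 to 0.15 without 1 animal. KITLG at 96 h (0.06) was -0.10 under upper-quartile scaling, -0.06 with age as a covariate, -0.06 without the 2 animals over 20 months, -0.01 over loci with 1 symbol, -0.06 without TP07 and -0.10 without TP17, in a range of -0.10 to 0.13 without 1 animal. The cause was not tested. Both count filters left every locus in place, so they say nothing about stability, and the alternatives for normalized values were not run because the table holds counts. No analysis paired by replicate number was possible because the groups share none. The ages in the labels match vehicle and 48 h animals, and age class as a block is the fit matched on them. Deviations from the group means correlated at 0.239 (TP07 and TP08), 0.275 (TP09 and TP10) and 0.121 (TP11 and TP12) for like ages and at -0.235 to -0.011 otherwise. Deviations within a group cancel, so higher values for like ages lower the others by construction. Animals of like age also have consecutive numbers, so age and the order of the animals cannot be told apart. The labels give the ages and state no pairing. With age class as a block 3227 loci were called at 48 h. At this depth and group size at most 10.1% of simulated 1.5-fold changes and 36.6% of 2-fold changes were recovered. Far fewer loci were changed in that simulation than were called at 48 h or at 96 h against vehicle. The adjusted threshold loosens as more loci change, so these shares do not hold for the real comparisons.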

Other observations

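Further gene families, 10 in each of 3 comparisons, were chosen by symbol after seeing the data. Subunits of the proteasome, which degrades proteins, rose in 30 of 38 cases at 48 h and in 19 at 96 h (camera adjusted p = 8.81e-22 and 5.26e-10, and adjusted p = 0.122 and 0.229 with an estimated correlation). Subunits of complex I of the respiratory chain rose in 32 of 37 cases at 48 h and in 27 at 96 h (camera adjusted p = 1.28e-27 and 3.43e-14, and adjusted p = 0.122 and 0.161 with an estimated correlation). Median log2 fold changes of proteasome and complex I subunits at 48 h were 0.59 and 0.65, and 0.47 and 0.53 under upper-quartile scaling. At 96 h they were 0.33 and 0.39, and 0.18 and 0.24 under that scaling. With the length correction 13 complex I subunits rose at 96 h. Mitochondrial ribosomal proteins rose in 36 of 65 cases at 48 h with 1 lower, and in 20 at 96 h (camera adjusted p = 1.05e-21 and 2.65e-09, and adjusted p = 0.122 and 0.237 with an estimated correlation). Their median at 96 h was 0.26, and 0.11 under upper-quartile scaling. Cytosolic ribosomal proteins rose in 3 of 74 cases at 48 h, with a median of 0.08 that was -0.05 under upper-quartile scaling and -0.04 with the length correction.

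Core histones, which package DNA, rose in 14 of 49 cases at 48 h and in 40 at 96 h, with medians of 0.37 and 1.32 (0.24 and 1.17 under upper-quartile scaling). Between 48 h and 96 h 25 rose, with a median of 0.94 that was 0.92 under upper-quartile scaling (camera adjusted p = 7.59e-32, and adjusted p = 0.122 with an estimated correlation). Histone genes include near-identical copies, so counts of single histone genes are uncertain. Tubulins rose in 6 of 11 cases at 48 h and 5 at 96 h (camera adjusted p = 2.7e-06 and 0.00107, and adjusted p = 0.122 and 0.168 with an estimated correlation), with a median at 96 h of 0.46 that was 0.3 under upper-quartile scaling. Chaperonin subunits rose in 3 of 7 cases at 48 h and 0 at 96 h, where the median of 0.03 was -0.12 under upper-quartile scaling. Solute carriers rose in 30 of 243 cases and fell in 7 at 48 h, with a median of 0.11 that was -0.02 under that scaling. The share that rose is near that of all symbols at 48 h (2051 of 14151). Zinc finger genes rose in 8 of 379 cases and fell in 14 at 48 h, with a median of -0.05 that was 0.06 with the length correction, where 16 rose and 7 fell. Of 17 protocadherins 0 passed edgeR's test at 48 h and 2 fell at 96 h.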
